A study of Mus musculus with 2 samples.

How the data were processed

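The series holds 2 libraries of ribosome-depleted total RNA from the nuclear fraction of C57BL/6J mouse bone-marrow-derived macrophages, the labels naming the fraction as nucleoplasmic RNA and its compartment as nucleus. Per the labels, the cells received Lipid A at 100 ng/ml for 12 h, were washed for 12 h and then received Lipid A at 100 ng/ml again for 10 min. Lipid A is the part of bacterial lipopolysaccharide that activates the receptor TLR4. The libraries are biological replicates 1 and 2 of this single condition. The labels give a starting quantity of 1 µg of nucleic acid for replicate 1 and 500 ng for replicate 2, and a size range of 250 to 400 for both. Both carry the same donor identifier and each its own biosample identifier, but the labels do not say whether the biosamples were separate cultures or animals, so any spread between them may be partly technical. Other fractions, times and untreated cells were not used here.

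Per the file headers, the deposited gene tables give for each gene an expected count, which is an estimated number of reads that need not be whole, and a TPM value. The authors' transcript tables of the first kind hold an expected count, a TPM and the percent of the gene's TPM assigned to each transcript, with the SD of the count that comes from assigning reads to transcripts. Per the deposited file descriptions, these tables and the gene tables were derived from an alignment to the transcriptome for the mouse assembly mm10 with GENCODE release M21. A second deposited transcript table per library, derived directly from sequence reads and an index, holds an estimated count and a TPM for each transcript. It is called the other quantification here. The column names are those that RSEM and kallisto write, but the quantifiers, the aligner and their versions are not given in the sources used here, nor is strandedness. The authors scaled TPM over every target of the table, and TPM therefore falls for each gene as the highest short RNAs take more of the total. Genes with an effective length of 0 in the gene tables, 4687 in replicate 1 and 5192 in replicate 2, are short and listed at a TPM of 0, which does not show absence.

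Gene symbols, gene types, transcript types and coordinates came from GENCODE M21 on mm10. The tables list 55536 genes, 26248 entries with a numeric identifier that name no gene, 96 spike-in sequences and 1 phiX sequence. Only genes entered library sizes and comparisons. The other entries held 1.06% of the expected counts in replicate 1 and 0.245% in replicate 2. Gene counts equalled the sums of their transcripts within 1 count in all 81881 entries that were compared, in both libraries. The other quantification covered 55450 of the 55536 genes, and comparisons with it used these.

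Both libraries formed 1 group, so the design holds no contrast between conditions. An exact two-sided test over 2 libraries cannot go below p = 0.5, and no test between libraries was made. A gene counted as detected at a TPM of at least 1 and an expected count of at least 10 in both libraries. Each of 34 gene lists was placed by its median log2(mean TPM + 1) among 10000 random lists of the same size from all protein-coding genes. Lists of noncoding RNAs and the sex-linked list received values only. Pairs of lists were compared by the difference of their medians, set among 10000 random reassignments of the members. Percentiles below 2.5 or above 97.5 are called low or high. They describe positions among genes, which are not replicates, and carry no p-value.

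The replicates were compared by the log2 ratio of normalised counts, replicate 2 over replicate 1. Expected counts were rounded to whole numbers for edgeR, TMM factors were taken over genes with a mean count of at least 10, and 0.5 was added to each count in a ratio. The TMM factors were 0.945 for replicate 1 and 1.06 for replicate 2. A list's median ratio was taken over its members annotated as protein-coding genes with a mean count of at least 10, so members of another gene type were left out. It was placed among 10000 random lists of protein-coding genes matched on mean expression in 20 classes. Ratios of the noncoding lists and the sex-linked list covered all their genes at that count. Genes past 2-fold were counted at a mean count of at least 50 over all genes and of at least 10 within a list. edgeR's common biological coefficient of variation came from an intercept-only fit. Retained-intron shares are the percent of a gene's TPM assigned to transcripts annotated as retained introns, over genes with both such a transcript and a protein-coding one and a TPM of at least 1 in both libraries.

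Gene lists, thresholds, designs and most alternatives were fixed before the data were examined. So was the rule for the genes that are named. It takes the 4 highest members of each list, undetected members of lists that are otherwise mostly detected (at most 4) and members past 2-fold between replicates (at most 2). It adds the 10 highest protein-coding and 10 highest other genes, the 5 genes most higher and the 5 most lower in replicate 2 at a mean count of at least 100, the 5 protein-coding genes furthest apart between quantifications, and 10 inflammatory genes chosen in advance. All 651 list symbols were matched to the annotation, 2 of them by a synonym. Genes named outside the rule are marked as such, and some genes that the rule takes are not reported here.

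The 95% intervals of shares are exact Clopper-Pearson intervals, and those of count ratios are exact too. They cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 allows up to 3 counts, which is 0.123 CPM in replicate 1 and 0.166 in replicate 2. Alternatives covered the detection limit, the pseudocount, DESeq2's size factors, total counts and TPM as scaling, filters on low counts, the background of the random lists, the other quantification and each replicate alone. The ratio calculation was tested on simulated data, with counts drawn from the real means of all 55536 genes. Shares past 2-fold were taken among the 11722 genes with a simulated mean count of at least 50. List percentiles were taken among 11724 protein-coding genes with one of at least 10. Of genes simulated at a 4-fold change 97% passed 2-fold, against 45.5% of those simulated at a 2-fold change and 4.15% of unchanged genes. A list placed at −0.5 was recovered at −0.47, a coefficient of variation of 0.225 was recovered as 0.245, and 7 of 100 unchanged lists fell outside the central 95%. Simulated genes varied independently with one common coefficient of variation. The simulation therefore cannot show how often a list of genes regulated together would fall outside that range. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.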

Results

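RNA of the nuclear fraction was sequenced from bone-marrow-derived macrophages that had been exposed to Lipid A, washed, and exposed to Lipid A again for 10 min. The single group held 2 biological replicates. Expected counts on genes summed to 24444219 in replicate 1 and 18051097 in replicate 2. Genes detected in both libraries numbered 11327, of which 9443 were protein-coding among 22028 annotated, 634 were TEC genes (an annotation class of loci that await experimental support), 318 were antisense genes and 216 were lincRNA genes. Replicate 1 alone gave 11788 detected genes and replicate 2 gave 12148. Values below are the authors' TPM, given as mean ± SD with n = 2 unless a replicate is named.

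A few nuclear noncoding RNAs took a large part of both libraries. Malat1, a nuclear long noncoding RNA on chromosome 19 (5795690 to 5802672, ENSMUSG00000092341.3), held 10.3% ± 0.726 (SD, n = 2) of the expected counts. Rn7sk, the 7SK RNA that holds back the elongation factor P-TEFb (chromosome 9, 78175303 to 78175633, ENSMUSG00000065037.1), held 6.10% ± 0.488. Rpph1, the RNA part of ribonuclease P, held 1.52% ± 0.385, and Neat1, the scaffold of paraspeckles, held 0.506% ± 0.0486. Protein-coding genes took 74.8% ± 1.21 of the counts, lincRNA genes 12.1% ± 0.839 and genes of the class that includes Rn7sk 7.19% ± 0.963.

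The same libraries looked different on the TPM scale, which divides by the effective length of a transcript. Rn7sk alone made up 33.03% ± 0.0670 (SD, n = 2) of the gene TPM, Rpph1 9.21% ± 3.07 and the 2 annotated entries of Rmrp at one locus 8.85% ± 0.786. Protein-coding genes held 21.1% ± 1.33 of the TPM. The other quantification, derived directly from reads, divided the TPM differently, in shares added after seeing the data. It put 11.0% ± 0.479 on Rn7sk, 12.0% ± 3.33 on protein-coding genes, 23.4% ± 8.38 on processed pseudogenes and 39.9% ± 14.6 on miRNA genes. Of its counts, miRNA transcripts held only 2.83% in replicate 1 and 1.04% in replicate 2. In the first quantification they held 5.28e-05% and 6.66e-05% of the counts, so the TPM share does not show abundant miRNA. Rn7s1 and Rn7s2, near-identical copies of the RNA of the signal recognition particle whose reads cannot be divided between them with certainty, together held 7.61% ± 2.66. Small nuclear RNA genes held 11.6% ± 0.252 of the TPM, against 0.207% ± 0.0414 of the counts. In the other quantification they held 1.65% ± 0.0643 of the TPM. Gm22513 stood at 13943 ± 764 TPM and Gm25939 at 8718 ± 1968 TPM in the gene tables. Their effective lengths in replicates 1 and 2 were only 8.24 and 5.71 bases for Gm22513 and 18.3 and 13.8 for Gm25939. These TPM values therefore rest on very small divisors. The 10 highest genes took 25.2% of the counts in replicate 1 and 23.4% in replicate 2. For Rn7sk the exact 95% binomial interval was 6.43% to 6.45% in replicate 1 and 5.74% to 5.77% in replicate 2.

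Mitochondrially encoded mRNAs, all 13 detected, took 3.03% ± 0.629 of the counts, led by mt-Co1 at 7238 ± 530 TPM. Among 9 long noncoding RNAs known for nuclear retention, 7 were detected, with Xist at 84.3 ± 19.0 TPM and Tug1 at 44.0 ± 4.07, and Meg3 and Miat listed at 0. All 15 mRNAs of a list known to be abundant in the cytoplasm were detected at a median of 512 ± 103 TPM (mean and SD of the replicates' medians), led by Psap (3177 ± 258) and Fth1 (1591 ± 497). The median of the nuclear-retained list lay below that of the cytoplasmic list by a log2 difference of −4.42 ± 0.86 in TPM and −0.90 in CPM, which does not divide by length.

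**Figure D1:**
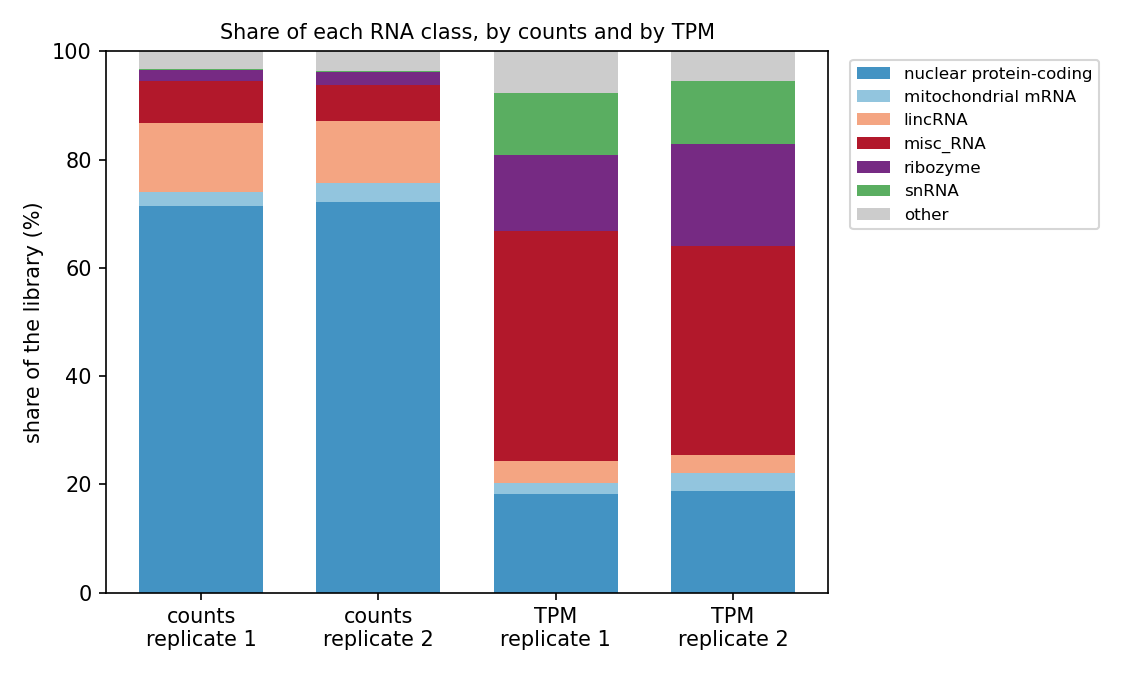
Share of expected counts and of gene TPM (percent, from 0) by gene class, as stacked bars for each replicate. Protein-coding genes took 74.8% of the counts and 21.1% of the TPM on average, and Rn7sk 6.10% and 33.03%.

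The nuclear RNA carried the transcripts of macrophages. Of 22 genes that mark macrophage identity, 21 were detected, with Lyz2 (lysozyme) at 960.7 ± 10.8 TPM, Ctss (cathepsin S) at 739 ± 144, Mpeg1 (perforin-2) at 649 ± 19.9 and Adgre1 (F4/80) at 395 ± 67.1. The exception was Cx3cr1, the fractalkine receptor, at 0.08 TPM in replicate 1 and 0.09 in replicate 2. The 24 lysosomal genes were all detected at a median of 123 TPM, led by Psap, Ctsb (1220.4 ± 124) and Ctsd (1213 ± 65.8), and the 17 genes of antigen presentation at a median of 50.8, led by H2-K1 (2079 ± 29.9) and H2-D1 (1317 ± 258). Gpnmb, a glycoprotein of lysosomal membranes, stood among the 10 highest protein-coding genes at 1359 ± 59.8.

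Markers of other lineages were near 0. None of 12 B and plasma cell markers, 10 mast cell, basophil and eosinophil markers or 12 fibroblast and stromal markers was detected. T and NK cell markers were detected for 2 of 16 genes, Cd4 (17.4 ± 3.94 TPM) and Il7r (5.61 ± 1.87), and neutrophil markers for 1 of 13, Csf3r (68.7 ± 2.04). Erythroid and megakaryocyte markers were detected for 2 of 12 (Pf4 at 16.2 ± 1.01 and Alas2 at 2.09 ± 0.269), endothelial and epithelial markers for 3 of 10 (Vwf 14.6 ± 4.47, Kdr 9.21 ± 5.48, Pecam1 1.19 ± 0.212), and dendritic cell markers for 2 of 11 (Bst2 165 ± 98.2, which is also on the interferon list, and Batf3 2.54 ± 1.47). The macrophage median exceeded those of the 8 other lineage lists by log2 differences of 6.07 to 6.45, each at or above the 99.995 percentile of random reassignments of the genes. These differences were taken from the mean TPM of the replicates. Single replicates gave smaller ones, 5.86 to 6.32 in replicate 1 and 5.77 to 6.06 in replicate 2, with an SD between replicates of at most 0.23.

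Interferon-stimulated genes formed the most highly expressed inflammatory list. All 42 were detected, at a median of 94.9 TPM, above all 10000 random lists. Rsad2 (viperin, chromosome 12, 26442746 to 26456452, ENSMUSG00000020641.16) stood at 810.3 ± 321 TPM, Ifit2 at 625 ± 90.4, Mx1 at 569.8 ± 206 and Ifit3 at 373 ± 77.8. Transcription factors of the NF-κB, IRF and STAT families were detected for 18 of 20 genes at a median of 28.4 TPM, led by Irf7 (320.5 ± 142), with Stat2 at 212 ± 25.9, while Irf4 and Stat4 were not detected. Antimicrobial and recognition genes were detected for 27 of 30 at a median of 22.4 TPM. Saa3, an acute-phase protein (chromosome 7, 46711998 to 46715700), led them at 1096 ± 831, and Acod1, which makes itaconate, stood at 160.1 ± 60.1.

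Cytokine and chemokine genes were split. Of 32 genes 19 were detected, with Ccl5 at 470.4 ± 305 TPM, Cxcl10 at 181 ± 120 (chromosome 5, 92346638 to 92348889), Ccl4 at 95.97 ± 37.3 and Ccl7 at 80.7 ± 9.77. Tnf, an early target of TLR4 signalling (chromosome 17, 35199381 to 35202007, ENSMUSG00000024401.14), was at 66.9 ± 19.3, Il10 at 9.22 ± 3.49 and Il1b at 6.45 ± 0.679. Il6 was below the detection limit at 0.415 ± 0.148, with 35 expected counts in replicate 1 and 18 in replicate 2, and Ifnb1 passed a TPM of 1 in replicate 1 only (3.02 against 0.68). The list median of 5.16 TPM lay at the 99.57 percentile of random lists. These were drawn from all protein-coding genes, of which only 42.9% were detected. A high percentile of a list level therefore need not mean a level above that of expressed genes. Detected protein-coding genes had a median of 7.99 TPM, above that of the cytokine list.

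Genes listed as TLR feedback regulators were detected for 26 of 29 at a median of 12.2 TPM, above all random lists. The housekeeping list, at a median of 19.8 TPM, also lay above all random lists. Cd274 (PD-L1) stood at 206 ± 7.16, Trim30a at 148 ± 28.5, Zfp36 (tristetraprolin, which destabilises cytokine mRNAs) at 54.7 ± 6.12 and Nfkbia, the inhibitor of NF-κB, at 49.8 ± 23.4. Tnfaip3 (A20) was at 37.9 TPM in replicate 1 and 30.5 in replicate 2, and Dusp4, Dusp5 and Cish were not detected in both. The TLR4 receptor complex and its kinases were detected for 27 of 28 genes at a median of 16.3 TPM, led by Ikbke (237 ± 18.6) and Tbk1 (47.0 ± 1.11), with Lbp as the exception.

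Immediate early genes, whose transcription starts within minutes of a stimulus, were detected for 14 of 25 at a median of 3.60 TPM. Klf6 (74.0 ± 7.21), Zfp36, Junb (39.5 ± 6.84) and Atf3 (36.4 ± 4.75) were the highest, while Fos was at 10.6 ± 8.43 and Egr1 at 1.83 ± 0.276. Their median lay at the 95.7 percentile of random lists, inside the central range, and below that of the interferon-stimulated genes by a log2 difference of −4.38 (SD 0.21 between replicates, below all reassignments). It lay below the feedback regulators by −2.10 (SD 0.58, percentile 0.465) and below housekeeping genes by −2.17 (SD 0.15, percentile 0.34). Immediate early and cytokine genes differed by −0.39, at the 39.0 percentile of reassignments, so no difference was shown between these lists. Feedback regulators exceeded cytokines by 1.14 (SD 0.21), at the 94.4 percentile, which also lies within the central range. All these differences were taken from the mean TPM of the replicates, which need not lie between the single replicates. In replicates 1 and 2 alone, immediate early genes lay at −4.71 and −4.41 against interferon-stimulated genes. They lay at −2.22 and −2.43 against housekeeping genes and at −0.58 and −0.66 against cytokine genes. From replicate 2 alone, the difference between immediate early genes and feedback regulators shrank to −1.58 and its percentile of 3.02 lay inside the central range. Untreated cells were not used here, so none of these levels is a response.

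**Figure D2:**
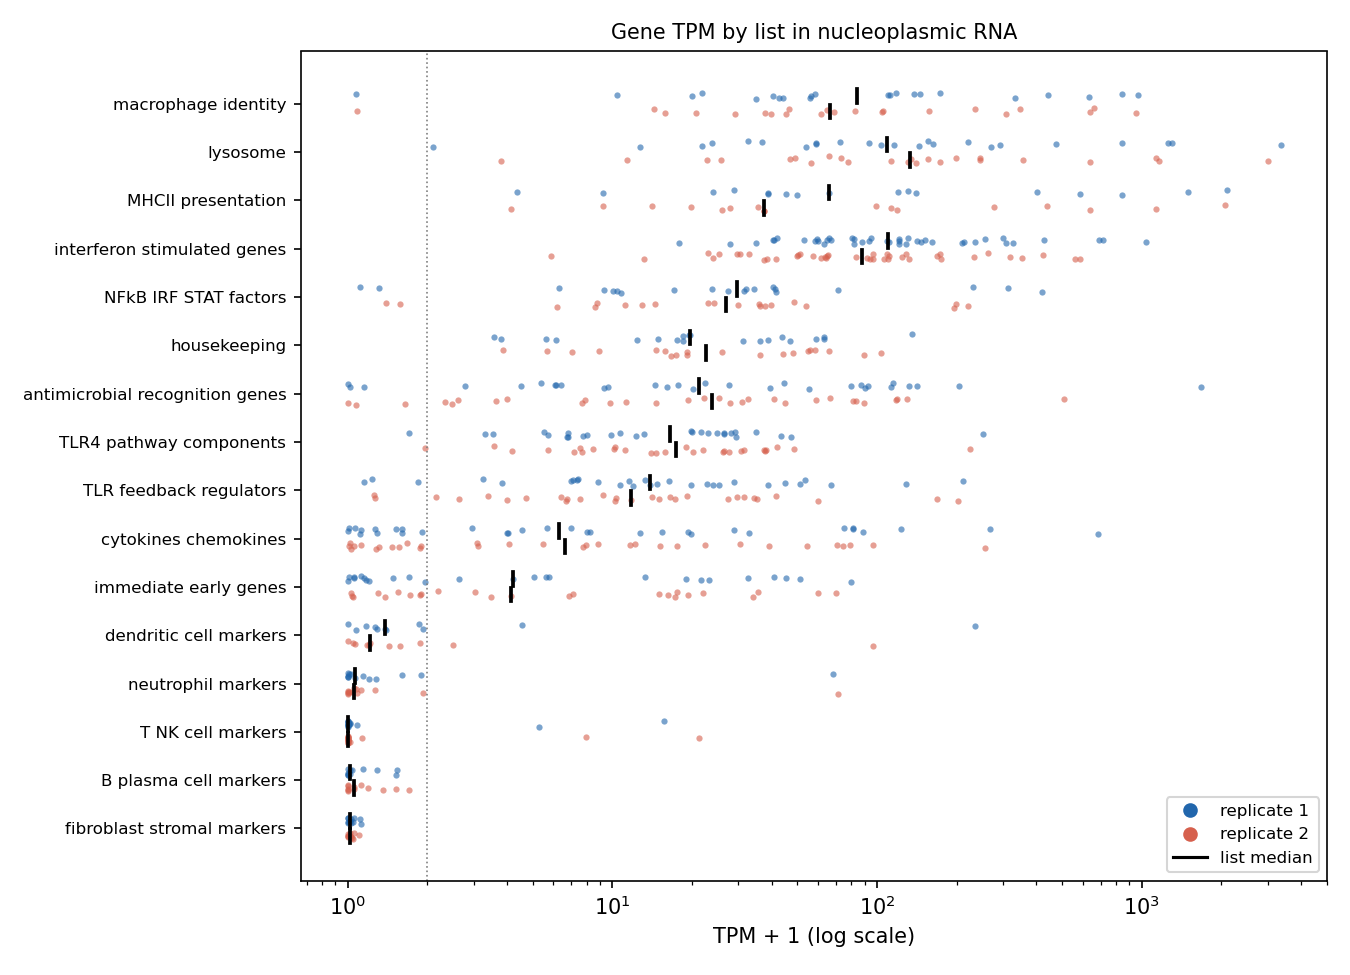
TPM + 1 on a log axis for each gene of each list, with a point for each replicate and a black tick at the list median; the dotted line marks the detection limit of 1 TPM. All 42 interferon-stimulated genes were detected, at a median of 94.9 TPM, against 0 of 12 B and plasma cell markers.

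The replicates differed in their inflammatory transcripts. Interferon-stimulated genes had a median log2 ratio of −0.68 (replicate 2 over replicate 1, 41 genes annotated as protein-coding), below all 10000 random lists of equal expression. Of these genes 13 lay more than 2-fold lower in replicate 2, 0 more than 2-fold higher and 2 lay above a ratio of 0. Tgtp1 had a log2 ratio of −2.18 (95% counting interval −2.36 to −2.00) and Isg15 one of −1.62. Antigen presentation genes had a median of −0.68 with 0 of 17 above 0, antimicrobial genes −0.53 with Saa3 at −2.00 and Cfb (complement factor B) at −2.08, feedback regulators −0.47 with Socs3 at −1.74 and Nfkbia at −1.22, and cytokines −0.42 with Cxcl10 at −1.74, Ifnb1 at −2.34 and Tnf at −0.84. Each of these 4 medians also lay below all random lists. Above a ratio of 0 lay 4 of 26 antimicrobial genes, 5 of 29 feedback regulators and 6 of 26 cytokine genes. Of these cytokine genes, 1 was more than 2-fold higher in replicate 2. NF-κB, IRF and STAT factors were lower too (−0.29, percentile 0.48), with Irf7 at −1.18. Dendritic cell markers moved with these lists, at a median of −1.17 over 9 genes (percentile 0.01, 5 more than 2-fold lower), Bst2 at −1.55 included. Of the 11 markers on that list only 2 were detected in both libraries. With 1 library on each side these ratios have no replicate check.

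Other groups went the opposite way or stood near 0. Mitochondrially encoded mRNAs were higher in replicate 2 (median log2 ratio 0.62, above all random lists), with mt-Nd2 at 1.32, and so were cholesterol synthesis genes (0.36, 17 of 20 above 0), with Msmo1 at 0.52. Reads of mitochondrial genes are shared with nuclear pseudogenes such as Gm28439 (log2 ratio 2.09), and mt-Nd4l, at −1.25, was higher in replicate 2 in the other quantification (0.93). TLR4 pathway components (0.03) and housekeeping genes (−0.04) stood in the central range, although Tfrc, the transferrin receptor, had a log2 ratio of 1.32. The immediate early list had a median of −0.06, but 5 of its 23 measured genes lay more than 2-fold higher in replicate 2. They were Fosb (4.36, 6 against 110 expected counts), Nr4a1 (3.17, 13 against 100), Egr2 (2.31), Fos (1.47) and Egr3 (1.37), of which Egr2 and Egr3, like Klf4 and mt-Nd4l, were named after their values were seen. Klf4, at −1.16, was the 1 member more than 2-fold lower. Its ratio was 0.16 by TPM, below the 0.24 to which TPM moved the median of all protein-coding genes. In the other quantification it turned to 0.04.

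Ribosomal protein genes, all 78 detected at a median of 26.5 TPM, had a median log2 ratio of −0.23 by TMM and 0.03 by TPM, where the median of all protein-coding genes moved to 0.24 and the list stood at −0.21 relative to it. The abundant cytoplasmic mRNAs (−0.50), lysosomal genes (−0.32) and macrophage identity genes (−0.30, with Cebpb at −1.88) were also low among lists matched on expression. Among lists matched on expression and gene length, a background added after seeing the data, these 4 lists lay inside the central range (percentiles 63.7, 12.9, 4.36 and 3.82). Replication-dependent histone genes were lower in replicate 2 (−0.88, 10 of 22 more than 2-fold), with Hist1h4i, the member highest in TPM, at −1.38. Cell cycle genes were higher at 0.41, but at 0.07 and inside the central range for members with a mean count of at least 50. Among the other lineage lists, endothelial and epithelial markers had a median of −0.91 over 4 genes, with Kdr at −1.52, a list median that turned to 0.21 in the other quantification.

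**Figure D3:**
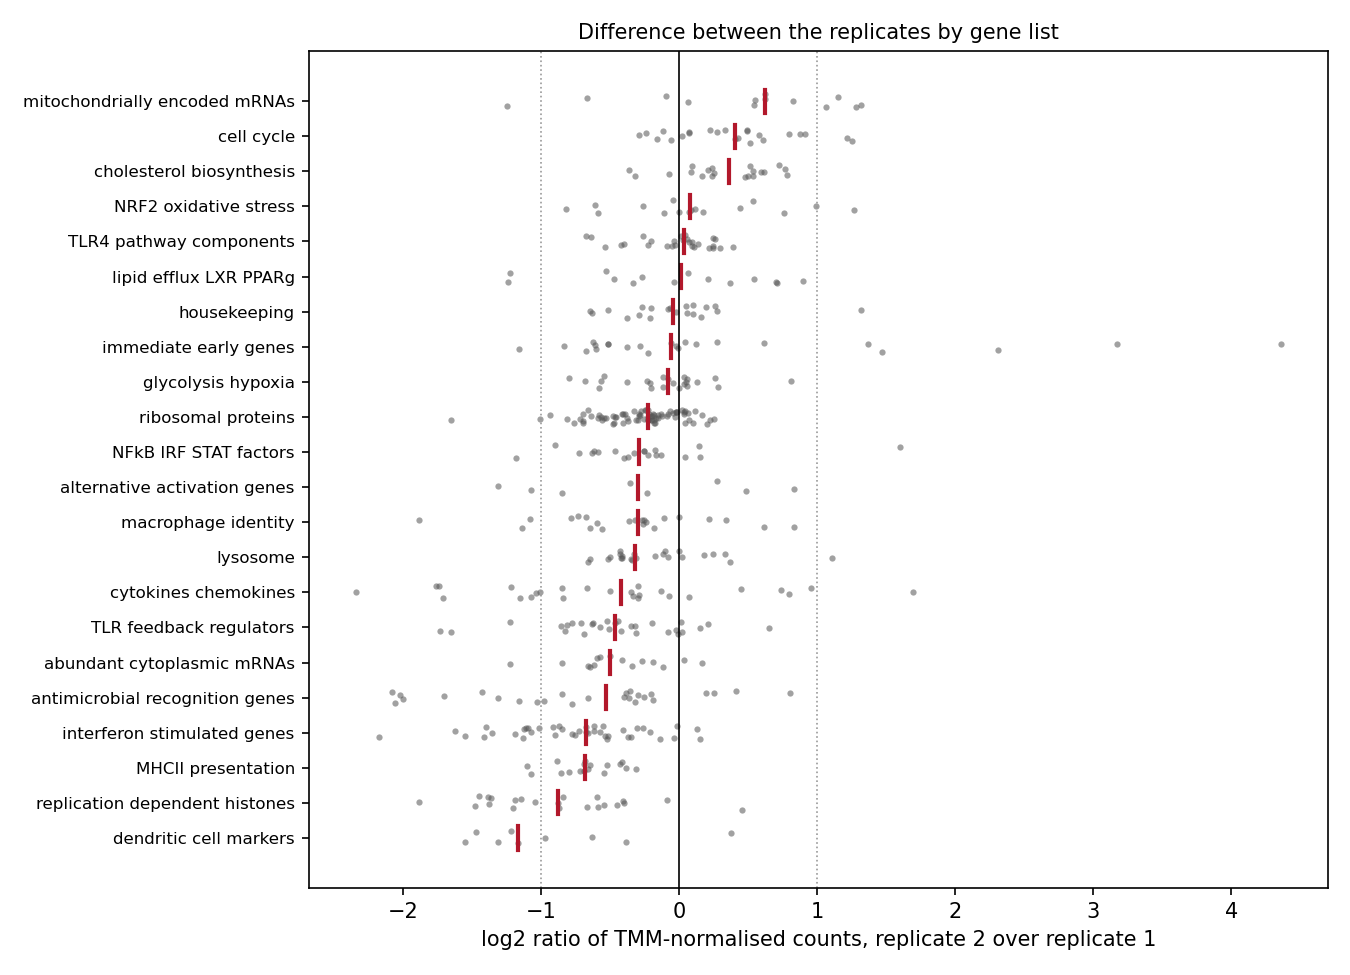
Log2 ratio of TMM-normalised counts, replicate 2 over replicate 1, for each protein-coding gene with a mean count of at least 10 (grey points), with a red tick at each list median and lines at 0 and at 2-fold either way. Interferon-stimulated genes had a median of −0.68 and cholesterol synthesis genes one of 0.36.

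Across single genes, 124 lay more than 2-fold higher and 353 more than 2-fold lower in replicate 2 among 11761 with a mean count of at least 50, so 26.0% of those past 2-fold were higher. Together they made up 4.06% of these genes, near the 4.15% of unchanged genes past 2-fold in the simulated data. That simulation took its spread from these same 2 libraries, so the number past 2-fold does not by itself show genes that differ. By TPM the numbers were 427 higher and 186 lower, 69.7% higher, but TPM moved the median of all protein-coding genes by 0.24, and relative to that median, a setting added after seeing the data, 177 were higher and 366 lower, 32.6% higher. In the other quantification 466 were higher and 467 lower among 17536 genes, 49.9% higher. Of the 5 genes most lower in replicate 2 at a mean count of at least 100, 4 were small nucleolar RNAs. They were Snora73b (log2 ratio −3.51), Snora73a (−3.41), Gm25776 (−3.19) and Snord22 (−3.62), whose TPM of 0 in replicate 2 stood against 29.9 expected counts. Scd1, a fatty acid desaturase (1.82), and Cenpa, the centromeric histone (1.68), were among the 5 most higher, beside Gm28439. The remaining extremes overlap other genes or copies and are uncertain. Gm37376 lies within Malat1 on the other strand and held 0 and 3910 counts, Gm49342 on chromosome 14 (50944517 to 50963136) held 657 and 0, and Zc3h11a (1.95) has 2 annotated entries.

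Replicate values on log2(TPM + 1) correlated across 23084 genes with Pearson's r = 0.965 and Spearman's rho = 0.930, and the log2 ratios had an SD of 0.49; genes are not independent replicates. Over 14749 protein-coding genes r was 0.984 and rho 0.980. edgeR's common biological coefficient of variation was 0.225 over 15439 genes. Shorter genes were lower in replicate 2, with a median log2 ratio of −0.24 in the shortest of 10 length classes of protein-coding genes and 0.10 in the longest.

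Transcripts annotated as retained introns, which are spliced incompletely, held 9.20% ± 0.512 (SD, n = 2) of the gene counts. Over 5973 genes that have both a retained-intron and a protein-coding transcript, the median share of the gene's TPM on retained introns was 26.7% over the means of each gene, from which the list values and percentiles were also taken, 26.4% in replicate 1 and 27.1% in replicate 2. Ribosomal protein genes had a lower share (16.1%, with 16.2% and 15.5% in the single replicates, below all 10000 random lists), as did lysosomal genes (12.6%, with 11.9% and 14.8%, percentile 0.985) and cholesterol synthesis genes (14.4%, with 14.5% and 13.6%, percentile 1.19). Interferon-stimulated genes (25.2%, with 25.5% and 24.9%) and NF-κB, IRF and STAT factors (32.6%, with 34.6% and 33.9%) lay in the central range. Single genes spread widely, with Irf7 at 60.3% ± 2.81, H2-K1 at 54.9% ± 13.8, Stat2 at 40.7% ± 0.861, Tnfaip3 at 32.7% ± 7.52, Il1b at 21.6% ± 2.77, Cxcl10 at 13.98% ± 0.245, Actb at 5.35% ± 0.400 and Nfkbia at 2.94% ± 1.40. The shares rest on how the authors' quantification divided reads among overlapping transcripts, and reads from introns outside annotated transcripts do not enter them.

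Malat1 showed such a division. Its normalised counts had a log2 ratio of −0.31, while its TPM was higher in replicate 2 (19978 against 12920). The transcript Malat1-201 was given 74.7% of the gene's TPM in replicate 1 and 44.5% in replicate 2. Across 55450 genes the 2 quantifications of one library correlated with Spearman's rho = 0.789 in replicate 1 and 0.770 in replicate 2. Over protein-coding genes, a restriction added after seeing the data, rho was 0.928 and 0.922. The protein-coding genes furthest apart were Gm17571, Gm11027, Gm10217, Gm21961 and Gm10563, all listed at 0 in the gene tables. In the other quantification they stood at 49.997, 106, 17.2, 14.8 and 28.2 TPM in replicate 1 and at 640, 140, 90.1, 84.6 and 69.7 in replicate 2. Their annotated lengths are 90 to 237 bases, and Gm17571 and Gm21961 have an effective length of 0 in the gene tables, so a 0 there does not show absence. Protein-coding genes as a whole were lower in TPM in the other quantification, by a median log2 difference of −0.78 in replicate 1 and −0.45 in replicate 2, and 0.16 higher in each after TPM was rescaled over them.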

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

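The values in this part were looked for outside the genes, in sequences that enter no comparison, and no test here was chosen after a result was seen. The phiX sequence, a bacteriophage genome commonly added to sequencing runs, held 262333 expected counts in replicate 1 and 44256 in replicate 2, above the 3 counts that a count of 0 allows. The other quantification gave it 288517 and 51665 counts. Entries with a numeric identifier, which name no gene, held 25 and 26 counts. The spike-in sequence ERCC-00099 held 8 counts in replicate 1 and 28 in replicate 2 in the other quantification, while the gene tables gave the spike-in sequences 0 counts in both replicates.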

How the results depend on the processing

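Of the settings below, random lists matched on both expression and length, the restriction of the quantification comparison to protein-coding genes, the shares of TPM in the other quantification and TPM ratios relative to their protein-coding median were chosen after the results were seen. DESeq2's size factors and total counts move all genes by one factor and cannot change a percentile of list ratios. They are left out of the counts that follow. Also left out are the pseudocount and rescaled TPM for list levels and rescaled TPM for differences between lists. These keep the order of genes wholly or nearly and can still move a percentile, but none crossed a limit. List levels kept direction and side of the limits in 152 of 167 comparisons with an alternative, list ratios in 86 of 95 and differences between lists in 67 of 70. In the other quantification the TPM of 520 of 671 list and named genes moved by more than the replicate SD, 437 to lower and 83 to higher values, and the median log2 difference of the 509 genes at a mean TPM of at least 1 was −0.93. There 79 of 98 named ratios past 2-fold stayed past it in the same direction, as did 64 of 98 by TPM in the first quantification. These TPM ratios of single genes were not set relative to the shift of all protein-coding genes by TPM. Retained-intron shares of 14 of 18 lists moved by more than the replicate SD in the other quantification, and their percentiles were computed for the first quantification only. Where no cause is given below, the cause was not tested.

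Detection at a TPM of 5 left 6328 genes, by its stricter limit. As shares of TPM, which divides by length, protein-coding genes took 21.1%, lincRNA genes 3.69%, the Rn7sk class 40.7%, ribozymes 16.4%, Malat1 1.65%, Rn7sk 33.03%, the 10 highest genes 64.2% and the 100 highest 82.3%. In the other quantification the shares of counts were 70.0%, 10.5%, 5.71%, 1.71%, 7.97% and 4.80% in the same order, and 23.0% for the 10 highest. Its shares of TPM were 12.0%, 1.85%, 13.5%, 4.84%, 0.864% and 11.0% in that order, 1.22% for mitochondrial mRNAs, 79.8% for the 10 highest and 86.8% for the 100 highest. Between replicates, Pearson's r was 0.947 with a pseudocount of 0.1 and 0.972 over detected genes, where Spearman's rho was 0.961. The SD of log2 ratios was 0.93 with that pseudocount, 0.38 over detected genes and 0.45 in the other quantification, whose coefficient of variation was 0.248.

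Percentiles of list levels crossed a limit in these cases. Against detected genes alone, which stand higher than all genes, immediate early genes moved to 97.6 and alternative activation genes to 98.5 (each over its detected members), NRF2 genes to 93.0, cell cycle genes to 0.190, cholesterol synthesis genes to 4.98 and histone genes to 36.0, the last pair turning from above to below the middle. With lists matched on length, cholesterol synthesis genes were at 94.3 and T and NK cell markers at 6.07. Histone genes were at 82.8 in CPM and 97.0 in the other quantification, where T and NK cell markers were at 4.24. Over single replicates, T and NK cell markers ranged from 3.57 to 5.14, cholesterol synthesis genes from 96.8 to 98.8, histone genes from 94.8 to 99.8, and the difference between immediate early genes and feedback regulators from −2.40 to −1.58. In CPM, feedback regulators exceeded cytokines by 1.73, past the upper limit, and nuclear-retained RNAs lay at −0.90 against cytoplasmic mRNAs.

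TPM moved the median log2 ratio of all protein-coding genes by 0.24 and total counts by 0.17. By TPM, lipid efflux genes were at 0.40 (0.16 relative to that shift), now high, and lysosomal genes at −0.0374 (−0.28 relative), no longer low. With random lists matched on expression and length, ribosomal protein genes at −0.23 stood above the middle of the lists, and abundant cytoplasmic mRNAs at −0.50, macrophage identity genes at −0.30 and lysosomal genes at −0.32 were no longer low. Endothelial and epithelial markers turned to 0.21 in the other quantification, and cell cycle genes stood at 0.0701 there and at 0.0709 at a mean count of at least 50. Genes past 2-fold numbered 427 higher and 186 lower by TPM, 474 and 829 at a mean count of at least 10, 42 and 184 at 200, as the filters take in more or fewer genes, and 466 and 467 in the other quantification. Among single genes, Klf4 was at 0.16 by TPM, below the shift of 0.24 in all protein-coding genes. It turned to 0.0392 in the other quantification, which also turned mt-Nd4l to 0.93 and Gm24497 to −0.82.

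The median retained-intron share was 31.7% in the other quantification. Between quantifications, rho was 0.634 over genes at a TPM of at least 1 in one and 0.925 over protein-coding genes, and r was 0.838 with a pseudocount of 0.1, 0.672 over genes at a TPM of at least 1 and 0.966 over protein-coding genes. Depth limits the low genes most, since Il6 and Fosb rest on 35 and 6 counts in replicate 1. No paired analysis was possible because the series holds a single group.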

Other observations

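All 3 patterns weighed here were noticed in the data before they were tested. The tests that compare interferon-stimulated with ribosomal protein genes and abundant cytoplasmic mRNAs, that count immediate early genes among random lists and that divide length classes by expression were chosen after the result was seen, while the length correction and the length difference in the other quantification were fixed before their outcome was seen.

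Several groups that the comparisons do not lead with were also measured. Xist was detected at 84.3 ± 19.0 TPM (SD, n = 2), while the Y-linked genes Ddx3y, Kdm5d and Eif2s3y had 0 counts and Uty 1 count in replicate 1; the labels give the sex as not collected. Genes of alternative activation were detected for 5 of 15, with Tgfb1 at 56.3 ± 5.18, Il4ra at 43.3 ± 13.2, Mrc1 at 31.7 ± 17.97 and Clec10a at 4.71 ± 1.70, and Retnla, Ccl17, Ear2 and Chil4 listed at 0, named here for that value. The list median of 0.440 TPM (0.45 in replicate 1 and 0.28 in replicate 2) lay at the 53.7 percentile of random lists. Their median log2 ratio between replicates was −0.30, inside the central range.

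Cell cycle genes were detected for 10 of 25 at a median of 1.12 TPM (percentile 72.1), led by Pcna at 21.7 ± 1.92. Histone genes were detected for 19 of 23 at a median of 6.77 (7.08 in replicate 1 and 3.77 in replicate 2, percentile 99.6). Cholesterol synthesis genes were detected for 19 of 20 at a median of 4.79 (percentile 97.9). Lipid efflux genes were all 14 detected at a median of 37.3, led by Apoe at 439 ± 205. Glycolysis and hypoxia genes were detected for 22 of 24 at 16.8, led by Hk3 at 176 ± 38.2, NRF2 genes for 15 of 18 at 11.4, led by Sqstm1 at 106 ± 15.9, and housekeeping genes for all 20 at 19.8. Of 14 inflammatory noncoding RNAs 8 were detected, with Lncpint at 89.5 ± 9.64 and Mir155hg, the host of miR-155, at 19.1 ± 11.8 and a log2 ratio of −1.60. Of 10 structured nuclear RNAs 7 were detected, Scarna2 at 669.5 ± 71.9 among them, and of 3 structured cytoplasmic RNAs 2, with Vaultrc5 not detected.

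Interferon-stimulated genes were lower in replicate 2, by a median log2 ratio of −0.68. A trend of the ratio with gene length is argued against as the whole cause, since it was too small. Medians of the length classes, at a mean count of at least 50, ran only from −0.24 to 0.10. After the medians of the length classes were subtracted, the list median was −0.73, below all random lists matched on expression and length. A trend of that size could not have brought the list into the central range, so the subtraction adds no further support. A larger carry-over of cytoplasmic RNA into replicate 1 stays open. Ribosomal protein genes stood above the interferon-stimulated genes by 0.45, past the upper limit of 0.24 from random reassignments. The abundant cytoplasmic mRNAs stood above them by only 0.18, inside the limit of 0.25. Among lists matched on expression and length, however, both cytoplasmic lists lay inside the central range (percentiles 63.7 and 12.9). Those random lists could draw members of both lists and other cytoplasmic mRNAs, which carry-over would lower too. That position therefore cannot separate carry-over from a trend with gene length. Mitochondrially encoded mRNAs were higher in replicate 2, at a median of 0.62. Mitochondrial ribosomal RNAs, in these ribosome-depleted libraries, went from 0.123% of the counts in replicate 1 to 0.0637% in replicate 2. Rn7s2 and Rn7s1, near-identical copies of a cytoplasmic RNA, were at −1.10 and −1.07. They are 300 bases long, and short nuclear classes fell too, such as small nuclear RNAs at a median of −0.79. Nuclear RNAs nearer to 300 bases differed among themselves. Rn7sk (331 bases) was at −0.33 and Rpph1 (319 bases) at 0.36. The 2 entries of Rmrp (271 and 281 bases), at one locus, were at −0.32 and −1.82. Dendritic cell markers fell with the interferon-stimulated genes, at −1.17 with 5 of 9 more than 2-fold lower. Only 2 of the 11 were detected in both libraries, Bst2, which is also on the interferon list, and Batf3 (72 against 30 counts). Their fall therefore rests mostly on genes below the detection limit. A difference in the cells stays open beside one in induction or handling, since no biological explanation was tested in a series of 1 group.

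Immediate early genes gave 5 members more than 2-fold higher in replicate 2 among 23. Spread that falls on each gene alone at that expression level is argued against, but not spread shared by genes regulated together, since 10000 random lists of equal expression held at most 4 such genes; at a mean count of at least 50, which leaves out Egr2 and Egr3, 3 of 17 members were past 2-fold and 5 of 10000 lists held as many. The list as a whole did not rise, with a median of −0.06, 9 of 23 members above 0, Junb at −0.61 and Atf3 at −0.52, and the counting interval of Egr3, 0.55 to 2.28, reaches below 2-fold. The cause stays open, and no biological explanation was tested.

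Short protein-coding genes were lower in replicate 2, with the shortest length class below the longest by a log2 difference of −0.35 over all expression levels. A difference in expression between length classes is argued against as the whole cause, since the difference was −0.35 in the lowest of 3 expression classes (95% resampling interval −0.44 to −0.26), −0.43 in the middle (−0.52 to −0.37) and −0.40 in the highest (−0.58 to −0.30). Division of reads by the authors' first quantification is argued against as the whole cause, since the difference was −0.29 in the other quantification (−0.32 to −0.26). Recovery of RNA that depends on length was not tested apart from these and stays open. Medians were −2.27 for small nucleolar RNAs (28 genes, SD over genes 1.66) and −0.82 for the Rn7sk class (6 genes, SD 1.39). They were −0.79 for small nuclear RNAs (24 genes, SD 0.68) and −0.50 for small Cajal body RNAs (5 genes, SD 0.45). The small Cajal body class as a whole rose from 0.146% of the counts in replicate 1 to 0.195% in replicate 2. Of 2 single short RNAs Rn7sk was at −0.33 and Rpph1 at 0.36. The replicates also differ in starting quantity, 1 µg against 500 ng, which cannot be separated from the replicate itself, and no biological explanation was tested.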
